A study of Caenorhabditis elegans with 8 samples.

How the data were processed

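Total RNA was sequenced from first-stage (L1) larvae of Caenorhabditis elegans in 4 genotypes, with 2 libraries (a and b) each, so 8 libraries in all. Per the labels, larvae hatched for 16 h in buffer, were fed for 2.5 h, and were sorted for animals without the green balancer. Libraries were made with a stranded total RNA kit and read as 50 bp single-end reads on a HiSeq 2500. The genotypes were wild-type, a cec-4 deletion mutant, a strain with an integrated transgene of lamin Y59C fused to GFP under the baf-1 promoter (with an unc-119 rescue marker in an unc-119 mutant background) and the strain with both, called the double mutant here. The labels do not say whether the libraries of a group came from separate cultures, so they may be technical replicates. No strain with a wild-type GFP-lamin transgene was analysed here, so the presence of the transgene, its marker and the unc-119 background go together with the lamin mutation in every comparison.

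The deposited count table held whole numbers per gene and library; the authors aligned reads with Bowtie to ce10 and used edgeR 3.24.0, per the submitters' processing notes. The counting tool, its annotation and whether it used the strand are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain. The deposited normalized table was on the log2 scale. All 163136 of its values were recomputed from the counts as the log2 of the count scaled to the mean library total plus a pseudocount of 8, and 0 differed by more than 1e-06; it was not used further. The table had 20392 genes under WormBase gene IDs, 1612 of them with 0 counts in all libraries. Symbols were found by ID for 19182 genes. Positions came from a WBcel235 annotation, matched by gene ID alone for 19870 genes; since the notes name ce10 for the alignment, these positions describe the gene in WBcel235 and no coordinate was converted. The 522 genes not in that annotation held 0.536% to 0.576% of the counts of a library.

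Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr (6037 genes, 0.0278% of all counts, leaving 14355), and libraries were scaled by TMM factors. The quasi-likelihood F-test (two-sided) was fitted to all 8 libraries with 1 mean per group. The 4 groups shared 1 estimate of the spread (common dispersion 0.00408, 4 residual and 6.03 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called changed at an adjusted p under 0.05. All adjusted p-values of genes in the text are from this test unless another tool is named. Fold changes are log2 values ± standard error (SE). This SE was worked back from the test, as the size of the change divided by the square root of its F statistic. It may be too small for genes of few counts. CPM values (counts scaled to TMM-adjusted library totals) are means ± SD (n = 2). The 6 comparisons were lamin Y59C against wild-type, the cec-4 mutant against wild-type, the double mutant against wild-type, lamin Y59C and the cec-4 mutant, and the interaction, which is the lamin effect without CEC-4 minus the lamin effect with it. In 20 simulations with no effect, a comparison gave between 0.4 and 1.2 calls on average, and at most 6. The fit was tested on simulated data with 200 changed genes per draw in 5 draws. Changed genes were drawn only from those with a mean of at least 1 CPM, so the recovery does not cover genes below that. At 2-fold it recovered 93.7% of changed genes for lamin Y59C against wild-type, 91.9% for the double mutant against lamin Y59C and 80.9% for the interaction; at 1.5-fold it recovered 72.8%, 73.4% and 45.4%. Unchanged genes called in these draws averaged 14, 15.2 and 13.4, which is over 5% of the calls even if all 200 changed genes had been called. All these simulations drew counts with the spread fitted here. Variation between libraries that the fit understates is not in them, so recovery may be lower and false calls more frequent in the data.

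The groups, comparisons, tests, gene lists and the rule for genes named in the text were set before the data were examined. The rule took the genotype genes lmn-1, cec-4, unc-119 and baf-1. For each comparison, among called genes with a mean of at least 5 CPM in a compared group and no overlap between the libraries compared (the interaction had no rule on overlap), it took the 10 largest rises and 10 largest falls that carry a genetic name and at most 2 per direction known by a sequence name. For each gene list, it took up to 4 called members by smallest adjusted p, or up to 2 as values where none was called. It also took up to 10 genes called in lamin Y59C and called the other way between the double mutant and lamin Y59C, and up to 10 interaction genes. The text gives part of these genes in full and counts the rest.

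Of 38 gene lists, the 35 with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it, camera with an estimated correlation and fry were run, and members were also counted with p-values adjusted over the list alone. Camera with an estimated correlation and the directional test of fry called 0 lists in every comparison, so each camera call of a direction in the text rests on the preset correlation. The mixed test of fry, which asks for changes in either direction, called 16 of 35 lists in lamin Y59C and 1 in the cec-4 mutant against wild-type. It called 22, 19 and 18 in the double mutant against wild-type, lamin Y59C and the cec-4 mutant, and 1 in the interaction. Genes on autosome arms (the outer 25% at each end) and centres were compared with Fisher's exact test (two-sided).

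The alternatives were DESeq2 size factors, no filter on low counts, a filter of 1 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, only the libraries compared, the replicate letter as a block, each library left out in turn, an adjusted p under 0.01, a fold of at least 2, and wider arms. One alternative was added after the data were seen, in which the deepest library was thinned to 32486340 counts, the mean total of the others. Leaving out a library leaves 1 library in its group, which is then assumed to vary like those of the other groups. Figures were drawn in Python 3.11.15.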

Results

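CEC-4 is a chromodomain protein that tethers methylated heterochromatin to the nuclear envelope, and the lamin mutation Y59C stands for a human mutation of Emery-Dreifuss muscular dystrophy. To ask how the loss of this anchor alters the expression changes that go with the mutant lamin, total RNA of L1 larvae was sequenced from wild-type, the cec-4 mutant, lamin Y59C, and the double mutant of lamin Y59C and cec-4, with 2 libraries (a and b) of each. The deposited counts summed to 32023667 and 57069281 in wild-type and to 30997254 and 36783388 in the cec-4 mutant. They summed to 30924676 and 31507437 in lamin Y59C, and to 32695286 and 32490114 in the double mutant. Between 17107 and 17569 genes had a count in a library, and the 10 most abundant genes held 5.61% to 6.28% of the counts. In a principal component analysis, the 4 libraries with the transgene lay at 8.70 to 17.5 on the first component (26.8% of the variance) and the other 4 at -22.7 to -4.98. Within groups, the Pearson correlation of log2 CPM across genes was 0.994 to 0.996, and genes are not independent replicates.

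The genes altered by the genotypes were examined first. Transcripts of cec-4 (WBGene00017990, IV:7575718-7577326, WBcel235) were at 13.6 ± 1.33 CPM in wild-type and 12.31 ± 0.0113 CPM in lamin Y59C. They were at 4.90 ± 0.194 CPM in the cec-4 mutant and 4.48 ± 0.181 CPM in the double mutant (SD, n = 2). The gene fell by 1.47 ± 0.11 (log2, SE) in the cec-4 mutant against wild-type (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000610). It fell by 1.46 ± 0.11 in the double mutant against lamin Y59C (adjusted p = 0.000371). The counts do not say which part of the gene the remaining reads came from. The transgene marker unc-119 (WBGene00006843, III:10902641-10908935) was at 22.97 ± 0.679 CPM in wild-type and 23.3 ± 1.36 CPM in the cec-4 mutant. It was at 41.6 ± 0.193 CPM in lamin Y59C and 43.2 ± 0.150 CPM in the double mutant. It rose by 0.86 ± 0.06 with the transgene in the presence of CEC-4 (adjusted p = 0.000280) and by 0.89 ± 0.06 in its absence (adjusted p = 0.000438). The lamin gene lmn-1 (WBGene00003052, I:8763041-8765631) was at 447 ± 8.05 CPM in wild-type, 451 ± 31.1 CPM in the cec-4 mutant, 515 ± 5.63 CPM in lamin Y59C and 506 ± 24.7 CPM in the double mutant. Its change in lamin Y59C of 0.20 ± 0.07 did not pass the test (adjusted p = 0.206). These counts do not separate the endogenous lmn-1 from the transgene. Transcripts of baf-1 (WBGene00000235, III:9467464-9468058), whose promoter drives the transgene, were at 61.7 to 67.8 CPM as group means and were not called in any comparison.

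**Figure D1:**
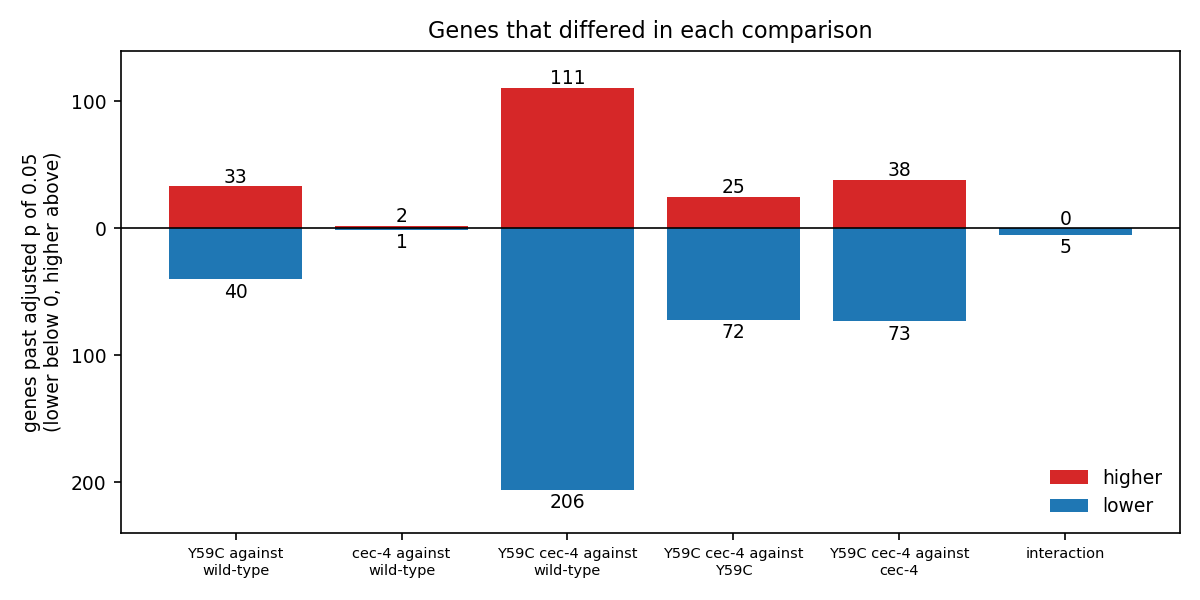
Number of genes called higher and lower (adjusted p under 0.05, edgeR quasi-likelihood test) in each comparison. The double mutant against wild-type had the most calls (111 higher and 206 lower), and the cec-4 mutant against wild-type had 3.

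Which transcripts differ when larvae carry mutant lamin was asked by comparing lamin Y59C with wild-type. The test called 73 of 14355 genes, 33 higher and 40 lower. At an unadjusted p under 0.05 there were 1004 higher and 1090 lower, and DESeq2 called 90 higher and 144 lower. The largest rise among genes named by the rule was in ani-2, an anillin homolog (WBGene00019608, II:6361159-6365367), from 8.04 ± 0.451 to 22.3 ± 1.16 CPM (1.47 ± 0.09, adjusted p = 5.58e-05). Called genes not covered by that ranking rose further, among them asp-16 (2.13). Another was R03G8.1 (8.75), which had no counts in wild-type, so its fitted change has no bound. The Sm-like RNA-binding gene lsm-5 (WBGene00003079, V:15570380-15570655) rose from 28.3 ± 0.0726 to 77.4 ± 1.51 CPM (1.45 ± 0.07, adjusted p = 8.45e-06). The gene tlp-1, which encodes a zinc-finger protein of tail and cell-fate patterning (WBGene00006580, IV:13701208-13704082), rose from 30.0 ± 0.199 to 80.5 ± 0.865 CPM (1.43 ± 0.06, adjusted p = 8.45e-06). The neuropeptide gene flp-3 rose from 52.4 ± 1.93 to 97.3 ± 3.94 CPM (0.89 ± 0.08, adjusted p = 0.00135). The F-box gene fbxa-95, which lies beside lsm-5, rose from 2.33 ± 0.210 to 5.68 ± 0.218 CPM (1.296 ± 0.14, adjusted p = 0.00617). Among fatty acid desaturases, fat-5 rose by 1.22 ± 0.19 (adjusted p = 0.0335) and fat-7 by 0.57 ± 0.08 (adjusted p = 0.0184). Genes that fell included the bestrophin gene best-5 (-1.06 ± 0.12, adjusted p = 0.00617) and the insulin-like gene ins-4 (-1.03 ± 0.17, adjusted p = 0.0398). The body-length regulator lon-1 (-0.54 ± 0.08, adjusted p = 0.0335) and the acetylcholinesterase gene ace-1 (-0.51 ± 0.08, adjusted p = 0.0318) fell as well. Of the 35 genes named by the rule and called here, 6 were called whichever library was left out (lsm-5, tlp-1, ani-2, unc-119, flp-3 and col-41). Without lamin Y59C a, best-5 and fbxa-95 were not called (highest adjusted p over the libraries left out 0.0616 for both). The call of fat-5 ended without either wild-type library, lamin Y59C a or either double mutant library (up to 0.253), and that of fat-7 without either wild-type library or lamin Y59C b (up to 0.144). That of ins-4 ended without wild-type a or either lamin Y59C library (up to 0.256), and those of lon-1 and ace-1 without any of the 4 libraries compared (up to 0.294 and 0.251). The number of calls was 16 without wild-type a, 178 without cec-4 a and 172 without cec-4 b. It was 8 without lamin Y59C a, 38 without lamin Y59C b, 45 without double mutant a and 47 without double mutant b. Without wild-type b the calls were about as many, but most of them were lower genes and most were not among the 73.

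Gene lists were used to ask whether muscle, cuticle and stress genes moved as groups in lamin Y59C. Of 55 body wall muscle genes, edgeR called 0. Of the same genes, 9 had an unadjusted p under 0.05, DESeq2 called 2 lower, and 0 passed when adjusted over the list alone. The median of that list was 0.01, its mean was -0.0040, and camera gave an adjusted p of 0.629 (adjusted p = 0.867 with an estimated correlation). The mixed test of fry, which asks for changes in either direction, passed for these genes (adjusted p = 0.0106), and its directional test did not (0.695). The ryanodine receptor gene unc-68 had -0.22 ± 0.06 (adjusted p = 0.136) and the twitchin gene unc-22 had -0.27 ± 0.07 (adjusted p = 0.138). Of 102 cuticle collagens, 2 were called higher and 9 lower (6 and 16 adjusted over the list alone), with a median of -0.14. Camera placed the collagens lower (adjusted p = 3.41e-05; adjusted p = 0.849 with an estimated correlation). Among collagens the smallest adjusted p was that of col-41 (WBGene00000618, X:15175032-15176481), with 52 and 118 counts in the wild-type libraries and 1 and 5 in lamin Y59C (-4.27 ± 0.42, adjusted p = 0.00326). It was followed by dpy-5 (-3.01 ± 0.34, adjusted p = 0.00621), rol-6, with 68 and 110 counts against 1 and 8 (-3.81 ± 0.47, adjusted p = 0.0107), and dpy-4 (-2.998 ± 0.40, adjusted p = 0.0170). Collagens are near-identical in part, so their counts may be shared between members. Without lamin Y59C a, dpy-5 was not called (highest adjusted p 0.0872). The genes rol-6 and dpy-4 were not called without wild-type a or lamin Y59C a (highest adjusted p 0.0726 and 0.0782). Camera also placed 14 hypoxia genes lower (median -0.23, adjusted p = 1.15e-05; adjusted p = 0.819 with an estimated correlation). Of these, edgeR called 0 and DESeq2 called 2 lower, while 9 had an unadjusted p under 0.05 and 9 were lower adjusted over the list alone. Of 20 osmotic stress genes, 0 were called higher and 2 lower (0 and 8 adjusted over the list alone). They were the adjacent and similar myo-inositol transporter genes hmit-1.1 (-1.07 ± 0.15, adjusted p = 0.0234) and hmit-1.2 (-0.86 ± 0.14, adjusted p = 0.0373). The list had a camera adjusted p of 0.00468 (adjusted p = 0.849 with an estimated correlation). The call of hmit-1.1 ended without either wild-type library or lamin Y59C a (up to 0.182), and that of hmit-1.2 without any wild-type, lamin Y59C or double mutant library (up to 0.313).

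**Figure D2:**
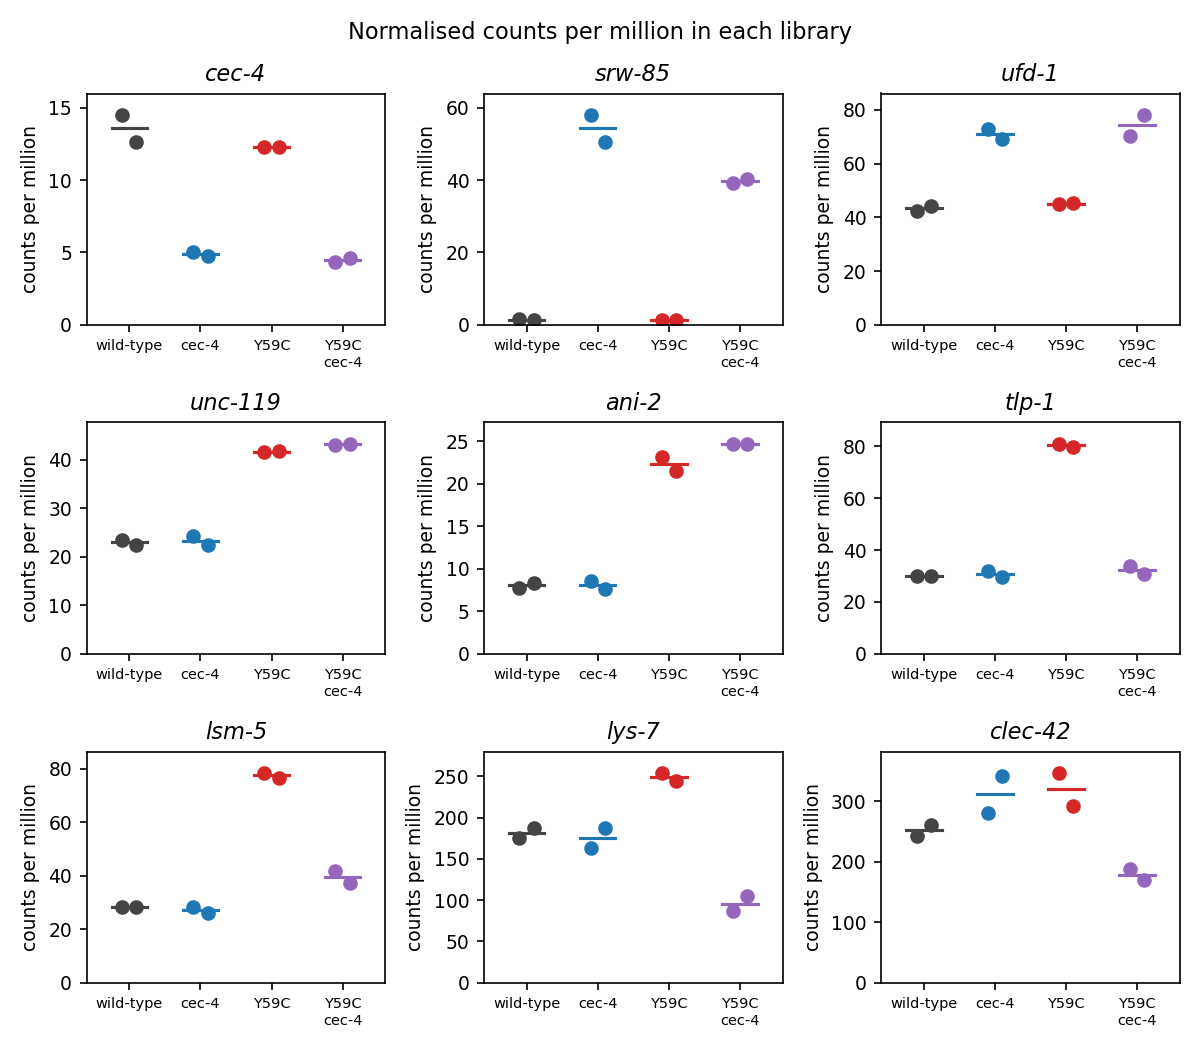
CPM of 9 genes in each of the 8 libraries (dots) with the group mean (line). srw-85 reached 54.4 CPM in the cec-4 mutant and 39.8 CPM in the double mutant, and tlp-1 reached 80.5 CPM in lamin Y59C.

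The effect of losing the anchor alone was asked by comparing the cec-4 mutant with wild-type. Only 3 genes passed the edgeR test, and DESeq2 called 11. One was cec-4 itself. The chemoreceptor-class gene srw-85 (WBGene00005832, V:19429387-19431136) rose from 1.41 ± 0.231 to 54.4 ± 5.37 CPM (5.31 ± 0.12, adjusted p = 8.55e-09). The gene ufd-1, a ubiquitin-dependent partner of CDC-48 (WBGene00006733, IV:12329408-12330890), rose from 43.3 ± 1.23 to 71.2 ± 2.58 CPM (0.71 ± 0.06, adjusted p = 0.00296). The srw genes form a large family of similar members, and how reads were shared among them is not known. Of 37 heterochromatin genes, cec-4 was the one called, and DESeq2 also called 1. Of 55 body wall muscle genes, edgeR called 0 and DESeq2 called 0, 2 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone (mixed test of fry, adjusted p = 0.508). Camera placed 7 lists lower with small shifts, led by 23 genes of the endoplasmic reticulum unfolded protein response (median -0.08, adjusted p = 0.000159; adjusted p = 0.913 with an estimated correlation). Of these, edgeR and DESeq2 called 0, 1 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The number of calls was 9 without wild-type b, and ufd-1 was not called without wild-type a (adjusted p = 0.0608; 0.00283 to 0.0608 over the libraries left out).

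The combined effect was asked by comparing the double mutant with wild-type. The test called 317 genes, 111 higher and 206 lower. At an unadjusted p under 0.05 there were 1191 higher and 1312 lower, and DESeq2 called 146 higher and 302 lower. Called genes included srw-85 (4.86 ± 0.12, adjusted p = 2.29e-08), ani-2 (1.61 ± 0.09, adjusted p = 3.18e-05) and flp-3 (0.97 ± 0.08, adjusted p = 0.000489). The desaturase gene fat-7 (WBGene00001399, V:7151353-7153146) rose from 39.5 ± 0.320 to 74.7 ± 4.33 CPM (0.92 ± 0.08, adjusted p = 0.000594). The glucuronosyltransferase gene ugt-16 rose from 47.9 ± 2.82 to 88.2 ± 6.62 CPM (0.88 ± 0.10, adjusted p = 0.00286). The lysozyme gene lys-7 (WBGene00003096, V:3481432-3482600) fell from 181 ± 8.78 to 95.7 ± 12.56 CPM (-0.92 ± 0.09, adjusted p = 0.00140). Likewise ins-4 changed by -1.41 ± 0.18 (adjusted p = 0.00497) and the aquaporin gene aqp-8 by -0.78 ± 0.08 (adjusted p = 0.00135). The uncharacterised gene Y53C12B.7 changed by -1.98 ± 0.13 (adjusted p = 0.000132). These 9 genes, cec-4, unc-119 and acs-19 were the 12 of 55 named calls that held whichever library was left out. The number of calls was 54 without wild-type a, 37 without double mutant a and 65 without double mutant b.

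Among gene lists in the double mutant, 16 of 193 detoxification genes were higher and 5 lower than in wild-type (37 and 15 adjusted over the list alone; camera adjusted p = 0.0321; adjusted p = 0.904 with an estimated correlation). Of 197 innate immunity genes, 4 were higher and 13 lower (8 and 31 adjusted over the list alone), with a median of -0.10 and a camera adjusted p of 0.00189 (adjusted p = 0.605 with an estimated correlation). Members that fell beside lys-7 were lys-2 (-0.45 ± 0.06, adjusted p = 0.00497), fipr-21 (-0.46 ± 0.06, adjusted p = 0.00502) and the saposin-like spp-18 (-0.63 ± 0.09, adjusted p = 0.00997). Of 14 hypoxia genes, 0 were higher and 5 lower (0 and 7 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 1.84e-06; adjusted p = 0.605 with an estimated correlation). The HIF-1 regulator rhy-1 fell from 7.49 ± 0.121 to 4.34 ± 0.022 CPM (-0.79 ± 0.12, adjusted p = 0.0133), and the sulfide oxidoreductase gene sqrd-1 changed by -0.77 ± 0.15 (adjusted p = 0.0345). Of 55 body wall muscle genes, the troponin gene unc-27 was the one called, at -0.27 ± 0.06 (adjusted p = 0.0490; 4 lower adjusted over the list alone; DESeq2 called 3 lower). It fell from 369.6 ± 5.36 to 307 ± 15.5 CPM, and camera gave an adjusted p of 0.0145 for the list (adjusted p = 0.773 with an estimated correlation; 0.000787 in the mixed test of fry). When libraries were left out, unc-27 was called without cec-4 a or cec-4 b alone, and its highest adjusted p was 0.285. Without double mutant a, lys-2 was not called (highest adjusted p 0.0644). Without wild-type a or double mutant a, fipr-21 was not called (0.0644), and spp-18, rhy-1 and sqrd-1 were not called without wild-type a, double mutant a or double mutant b (0.0985, 0.104 and 0.183).

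Whether loss of CEC-4 shifts expression in the lamin mutant was asked by comparing the double mutant with lamin Y59C. The test called 97 genes, 25 higher and 72 lower. At an unadjusted p under 0.05 there were 855 higher and 1042 lower, and DESeq2 called 92 higher and 148 lower. Both genes called in the cec-4 mutant besides cec-4 rose here too. Transcripts of srw-85 rose from 1.40 ± 0.0235 to 39.8 ± 0.686 CPM (4.82 ± 0.12, adjusted p = 3.97e-08) and those of ufd-1 from 45.1 ± 0.352 to 74.3 ± 5.68 CPM (0.72 ± 0.07, adjusted p = 0.00155). Their interaction values were -0.49 ± 0.20 (adjusted p = 0.471) and 0.00 ± 0.09 (adjusted p = 0.994). In the double mutant srw-85 was nevertheless called lower than in the cec-4 mutant (-0.45 ± 0.08, adjusted p = 0.0373), a value added after it was seen. That call ended without cec-4 a or either double mutant library (up to 0.238). From lamin Y59C to the double mutant, tlp-1 fell from 80.5 ± 0.865 to 32.4 ± 2.195 CPM (-1.31 ± 0.07, adjusted p = 1.40e-05) and lsm-5 from 77.4 ± 1.51 to 39.7 ± 3.17 CPM (-0.97 ± 0.07, adjusted p = 0.000201). The lysozyme gene lys-7 fell from 249 ± 7.29 to 95.7 ± 12.56 CPM (-1.38 ± 0.09, adjusted p = 0.000201). With cec-4, these 5 genes were the 6 of 40 named calls that held whichever library was left out. The asparagine synthetase gene asns-2 rose from 95.4 ± 20.1 to 212 ± 9.34 CPM (1.15 ± 0.17, adjusted p = 0.0233). Further, ugt-16 rose by 0.79 ± 0.10 (adjusted p = 0.0122), and fat-5 fell from 33.2 ± 5.86 to 13.1 ± 1.17 CPM (-1.35 ± 0.20, adjusted p = 0.0228). None of these last 3 was called without lamin Y59C a, double mutant a or double mutant b (highest adjusted p 0.168, 0.104 and 0.182). Of 102 collagens, 6 were higher and 7 lower (14 and 15 adjusted over the list alone), with a median of -0.16 and a mean of 0.26 (camera adjusted p = 0.679; adjusted p = 0.970 with an estimated correlation). Without 2 collagens at 0 counts in all libraries of a group, whose fitted changes have no bound, the mean was 0.14. Here col-41 rose by 3.76 ± 0.46 (adjusted p = 0.0122) and rol-6 by 3.46 ± 0.50 (adjusted p = 0.0220). Neither was called without the same 3 libraries (highest adjusted p 0.105 and 0.142). Of 197 innate immunity genes, 0 were higher and 8 lower (8 and 26 adjusted over the list alone; camera adjusted p = 2.4e-05; adjusted p = 0.569 with an estimated correlation). Of 55 body wall muscle genes, edgeR called 0. Of these, 11 had an unadjusted p under 0.05, DESeq2 called 2 lower and 0 passed adjusted over the list alone (camera adjusted p = 0.0326; adjusted p = 0.902 with an estimated correlation), and the mixed test of fry gave 0.0146. The number of calls was 157 without cec-4 a, 166 without cec-4 b, 8 without lamin Y59C a, and 6 without either double mutant a or double mutant b.

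It was then asked whether the 73 genes called in lamin Y59C lay nearer to wild-type in the double mutant. Of these, 51 (69.9%, exact Clopper-Pearson 95% interval 58% to 80.1%) had a smaller change against wild-type in the double mutant, 26 of 33 higher genes and 25 of 40 lower genes. Across the 73 genes, which are not independent, the slope of the double mutant's changes on those of lamin Y59C was 0.547. It was 0.978 over the 33 higher genes and 0.237 over the 40 lower genes. These slopes lean on 2 genes at 0 counts in all libraries of a group, whose fitted changes have no bound. Over the other 71 genes the slope was 0.333, with 0.431 for the higher and 0.304 for the lower genes. Between lamin Y59C and the double mutant, 17 of the genes were called in the opposite direction, 10 of them higher and 7 lower in lamin Y59C, and 2 were called further away. Besides tlp-1, lsm-5, col-41, rol-6 and fat-5, the genes called back included dpy-5 (2.67 ± 0.36, adjusted p = 0.0172) and sqt-3 (2.33 ± 0.34, adjusted p = 0.0220) among collagens and the heat shock gene hsp-17 (-0.40 ± 0.06, adjusted p = 0.0244). These 3 were not called without lamin Y59C a, double mutant a or double mutant b (highest adjusted p 0.160, 0.163 and 0.165), nor hsp-17 without lamin Y59C b. Of the 73 genes, 35 were also called in the same direction in the double mutant against wild-type, among them ani-2 at 24.7 ± 0.0635 CPM and flp-3 at 102.5 ± 3.34 CPM. They include lsm-5, which was called back but stayed higher than in wild-type (0.49 ± 0.07, adjusted p = 0.00955). Genes selected for a change in the lamin Y59C libraries tend to lie nearer to wild-type in another group by chance. In the simulation set beforehand, with no effect of cec-4 in lamin Y59C and every gene at its group mean, the share was 69.5% and reached the observed one in 15 of 40 draws, but that simulation called 1030 genes. A simulation chosen after that was seen, with effects in called genes alone, gave 71.0 calls and a share of 56.4% (44.9% to 68.2%), which reached the observed one in 0 of 40 draws. The number called back was at most 5 in the first and 2 in the second, and the slope was 0.886 and 0.980. The second simulation took the observed means of genes already called as their true effects. Its share and slope therefore hold little of the selection described above. Its 0 of 40 draws cannot decide whether the observed share exceeds what selection alone gives. The share was 42.3% without wild-type b and 37.5% without lamin Y59C a. The slope was 0.869 without wild-type a, 0.801 without wild-type b, 0.366 without lamin Y59C a and 0.358 without lamin Y59C b. The number called back was 7 without wild-type a, 33 without cec-4 a and 32 without cec-4 b. It was 2 without lamin Y59C a, double mutant a or double mutant b. No simulation was run with a library left out.

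**Figure D3:**
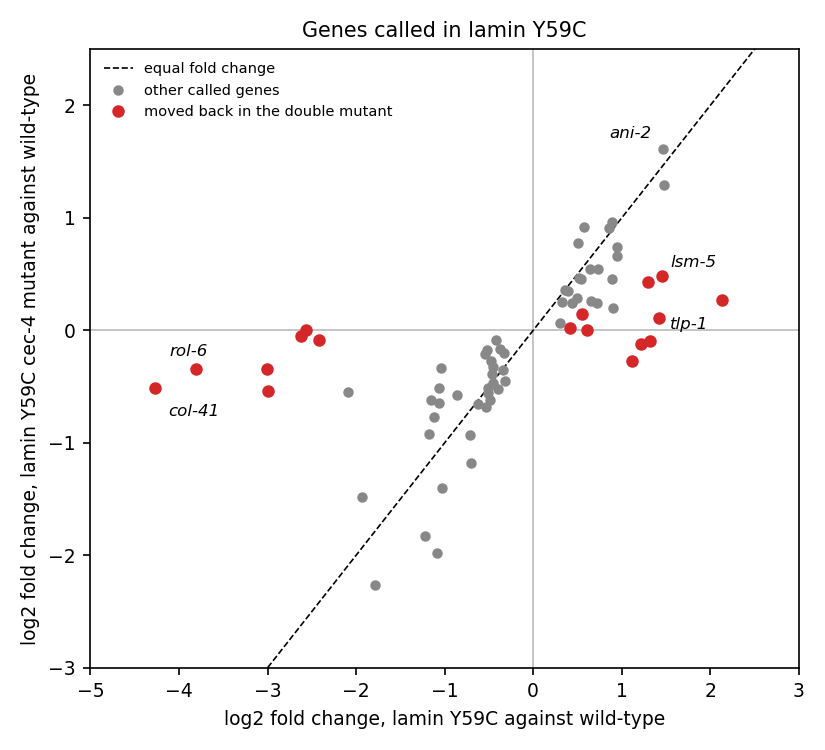
Log2 fold change against wild-type in the double mutant (vertical) and in lamin Y59C (horizontal) of 71 genes called in lamin Y59C; 2 genes with 0 counts in all libraries of a group are not drawn, and the dashed line marks equal changes. The 17 genes called back between lamin Y59C and the double mutant are in red, with tlp-1 and lsm-5 below the line and col-41 and rol-6 above it.

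The lamin effect in larvae that lack CEC-4 was asked by comparing the double mutant with the cec-4 mutant. The test called 111 genes, 38 higher and 73 lower. At an unadjusted p under 0.05 there were 858 higher and 1030 lower, and DESeq2 called 93 higher and 157 lower. Here ani-2 rose from 8.09 ± 0.674 to 24.7 ± 0.0635 CPM (1.61 ± 0.09, adjusted p = 7.74e-05). The acyl-CoA synthetase gene acs-2 (WBGene00009221, V:15567394-15569897) rose from 6.19 ± 0.314 to 26.5 ± 9.55 CPM (2.097 ± 0.26, adjusted p = 0.00888). The tyrosine aminotransferase gene tatn-1 fell from 247 ± 10.9 to 136 ± 5.00 CPM (-0.86 ± 0.09, adjusted p = 0.00368) and lys-7 from 175 ± 17.2 to 95.7 ± 12.56 CPM (-0.87 ± 0.09, adjusted p = 0.00558). The change was -0.66 ± 0.08 for aqp-8 (adjusted p = 0.00874) and -1.67 ± 0.13 for Y53C12B.7 (adjusted p = 0.000911). Of 38 named calls, ani-2, unc-119, Y53C12B.7, lys-7 and aqp-8 held whichever library was left out. Without cec-4 b, acs-2 was not called (adjusted p = 0.0506; 0.00561 to 0.0506 over the libraries left out). Without double mutant b, tatn-1 was not (adjusted p = 0.0521; 0.00257 to 0.0521). Of 193 detoxification genes, 7 were higher and 2 lower (25 and 8 adjusted over the list alone; camera adjusted p = 0.00169; adjusted p = 0.674 with an estimated correlation). Of 197 innate immunity genes, 1 was higher and 10 lower (10 and 27 adjusted over the list alone; camera adjusted p = 0.000321; adjusted p = 0.674 with an estimated correlation). Of 55 body wall muscle genes, edgeR called 0 and DESeq2 called 0, 6 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone (camera adjusted p = 0.0207; adjusted p = 0.674 with an estimated correlation), and the mixed test of fry gave 0.0213. The number of calls was 36 without cec-4 b, 33 without double mutant a and 11 without double mutant b.

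The interaction asked directly whether the lamin effect differs with and without CEC-4. The test called 5 genes, 0 higher and 5 lower. At an unadjusted p under 0.05 there were 651 higher and 792 lower, and DESeq2 called 35 higher and 40 lower. The lamin effect on tlp-1 was 1.43 with CEC-4 and 0.07 without it (difference -1.35 ± 0.09, adjusted p = 0.000643). For lsm-5 it was 1.45 with CEC-4 and 0.55 without (-0.90 ± 0.10, adjusted p = 0.0161), and for lys-7 it was 0.46 and -0.87 (-1.33 ± 0.13, adjusted p = 0.00983). The C-type lectin gene clec-42 (WBGene00008891, V:18191412-18194168) was at 252 ± 12.01 CPM in wild-type, 311 ± 43.1 CPM in the cec-4 mutant, 320 ± 38.6 CPM in lamin Y59C and 179 ± 12.5 CPM in the double mutant, with lamin effects of 0.35 and -0.80 (-1.15 ± 0.15, adjusted p = 0.0476). The claudin-like gene clc-11 (WBGene00009710, V:16138760-16139629) was at 10.6 ± 0.851, 16.489 ± 0.0817, 13.5 ± 1.39 and 9.73 ± 0.320 CPM in the same order, with effects of 0.34 and -0.76 (-1.11 ± 0.14, adjusted p = 0.0476). Against wild-type, clc-11 had 0.63 ± 0.10 in the cec-4 mutant (adjusted p = 0.212) and -0.13 ± 0.10 in the double mutant (adjusted p = 0.541). The effect on ani-2 had an interaction of 0.15 ± 0.12 (adjusted p = 0.721). The differences for col-41 (3.68 ± 0.54, adjusted p = 0.0897), fbxa-95 (-1.09 ± 0.21, adjusted p = 0.134), fat-5 (-1.55 ± 0.28, adjusted p = 0.131) and acs-2 (1.34 ± 0.35, adjusted p = 0.269) did not pass. With single libraries left out, tlp-1 was called each time, and lys-7 was not called without wild-type a or lamin Y59C a (highest adjusted p 0.0699). The gene lsm-5 was not called without wild-type a, wild-type b, lamin Y59C a or double mutant b (0.131). The gene clec-42 was called only without cec-4 a or lamin Y59C b (0.300), and clc-11 only without lamin Y59C b (0.232). The number of calls was 2 without wild-type a, 10 without cec-4 a and 3 without cec-4 b. It was 1 without lamin Y59C a, 35 without lamin Y59C b, 3 without double mutant a and 2 without double mutant b.

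How far the comparisons shared genes was asked next. Lamin Y59C and the double mutant, both against wild-type, shared 16 higher and 19 lower genes, where independent lists would share 0.255 and 0.574. Fold changes across genes correlated at r = 0.511 with a covariance of 0.0525; 20 simulations of unchanged groups against the same controls gave 0.450 and 0.0182. Part of the excess may come from the shared controls. The cec-4 mutant and the double mutant against wild-type shared 2 higher and 1 lower genes (0.0155 and 0.0144 for independent lists). Here r was 0.433 and the covariance 0.0325, against simulated values of 0.460 and 0.0183, and the same limit applies. Lamin Y59C and the cec-4 mutant against wild-type, which share only the controls, had 0 called genes in common. Their covariance was nearly as high, at 0.0310 against 0.0183 simulated (r of 0.411 and 0.459). The simulations may therefore hold too little variation of the shared controls. The excess of 0.0325 over 0.0183 cannot be read as a shared cec-4 effect. Without shared libraries, the lamin effects with CEC-4 and without it shared 8 higher and 9 lower genes, where independent lists would share 0.0874 and 0.203, with r = 0.220 and a covariance of 0.0215 (20 simulations gave -0.00178 and -7.75e-05). These 17 genes included ani-2, unc-119, flp-3, fat-7, lsm-5, ins-4, lon-1 and Y53C12B.7. Another of them was R03G8.1, at 0 counts in wild-type and the cec-4 mutant. Its fitted changes of 8.75 and 10.4 have no bound and raise the r and covariance, which were not computed without it. The cec-4 effects in the wild-type and lamin Y59C backgrounds, again without shared libraries, had srw-85 and ufd-1 in common as higher and cec-4 as lower, where independent lists would share 0.00348 and 0.00502. Across genes r was 0.0206 with a covariance of 0.00153 (20 simulations gave 0.00104 and 4.29e-05). This small covariance leans on srw-85, with changes of 5.31 and 4.82, so it does not show agreement across the other genes.

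Because CEC-4 binds chromatin enriched on autosome arms, the positions of called genes were compared. In the double mutant against wild-type, 89 of 4742 tested arm genes (1.88%) and 179 of 7186 centre genes (2.49%) were called, an odds ratio of 0.749 (0.572 to 0.974, Fisher's exact test, two-sided, unadjusted p = 0.0272). The odds ratio was 1.02 for the double mutant against the cec-4 mutant (exact p = 0.915) and 0.799 for it against lamin Y59C (exact p = 0.364). It was 0.722 for lamin Y59C against wild-type (exact p = 0.253). Split into higher and lower genes, none of 8 such tests passed (smallest adjusted p 0.226). Neighbouring genes are not independent, which makes these p-values too small. The odds ratio of 0.749 was 0.545 without wild-type a, 0.805 without wild-type b and 0.501 without double mutant a, none of them past the threshold, and 0.453 without double mutant b, which passed (unadjusted exact p = 0.0131). Against lamin Y59C, the odds ratio of 0.799 was 1.51 without lamin Y59C a (exact p = 0.721) and 1.504 without either double mutant library (exact p = 0.689). Against the cec-4 mutant, that of 1.02 was 0.430 without double mutant b (exact p = 0.331).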

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

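Of the tests in this part, the one on transcription running on from acs-2 and the counts of single and of remaining neighbouring pairs were chosen only after the result was seen. Comparing the lamin effect between strains with and without CEC-4 by an interaction test singled out 5 genes. The lamin effect was lower without CEC-4 by a log2 difference of -1.35 for tlp-1, -1.33 for lys-7, -0.90 for lsm-5, -1.11 for clc-11 and -1.15 for clec-42. In tlp-1 and lsm-5 the lamin effect was a rise with CEC-4 present that was smaller without it, while in lys-7, clc-11 and clec-42 the called effect was a fall without CEC-4 (-0.87, -0.76 and -0.80), and the effect with CEC-4 present did not pass (adjusted p = 0.0657, 0.160 and 0.175; edgeR quasi-likelihood test). For clc-11 that fall was from 16.489 CPM in the cec-4 mutant to 9.73 CPM, beside 10.6 CPM in wild-type. Its call ended without cec-4 b or either double mutant library (adjusted p up to 0.0999), and that of clec-42 without either double mutant library (up to 0.136). With single libraries left out, the adjusted p of the interaction reached at most 0.0103 for tlp-1, 0.0699 for lys-7, 0.131 for lsm-5, 0.300 for clec-42 and 0.232 for clc-11.

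In lamin Y59C, lsm-5 rose together with its neighbour fbxa-95 on the same strand of chromosome V, with acs-2 on their other side. Chance placement cannot be told apart from a shared cause. Of the genes called in lamin Y59C, 5 pairs lay within 10 kb of each other, where random sets gave 0.788 on average, and 9e-04 of 10000 sets gave as many. This had been set beforehand as speaking against chance, but the count includes the pair that raised the question, and the other pairs say nothing about it. At least 1 pair was found in 54.8% of the sets. Besides this pair and the similar hmit-1.1 and hmit-1.2, 3 pairs were left, as many as in 4.43% of the sets, but 2 of them share him-5, and the random sets hold no neighbours that move together or share reads. Transcription running on from acs-2 at a fixed share was argued against. The rise over wild-type was 49.1 CPM in lamin Y59C and 11.3 CPM in the double mutant for lsm-5, and 3.34 and 0.780 CPM for fbxa-95. At a fixed share these rises follow the rise of acs-2 over wild-type, so acs-2 would have had to fall from lamin Y59C to the double mutant. Between these groups acs-2 changed by 0.54 ± 0.23 (adjusted p = 0.352). Against wild-type it changed by 0.75 ± 0.24 in lamin Y59C (adjusted p = 0.197) and by 1.29 ± 0.24 in the double mutant (adjusted p = 0.0257). Its libraries overlapped, at 15.8 and 20.6 CPM in lamin Y59C and 19.7 and 33.2 CPM in the double mutant. A change in how far transcription runs on was not tested. Use of the strand in counting is not known, so reads shared between neighbours stay open, as does an effect of the lamin genotype or of a variant in the strain's background, neither of which was tested. tlp-1 lies on another chromosome, and no technical explanation was tested for it.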

How the results depend on the processing

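Of the settings here, thinning the deepest library was chosen after the data were seen. Counts of called genes are given in the order lamin Y59C against wild-type, cec-4 mutant against wild-type, double mutant against wild-type, against lamin Y59C and against the cec-4 mutant, and interaction. The reported counts were 73, 3, 317, 97, 111 and 5. With DESeq2 size factors, all 176 calls of named genes held. They also held with no filter and with wild-type b thinned to 32486340 counts, where 78, 3, 328, 106, 114 and 5 genes were called and the share nearer wild-type was 69.2%. A filter of 1 CPM kept 170 of the named calls, the DESeq2 test 174 of 175 and the compared groups alone 164 of 171, and 0 changed direction under any setting. With no filter, 159 genes were called in lamin Y59C against wild-type, 1.8e+02 (62 higher and 120 lower) in the double mutant against lamin Y59C, 212 in it against the cec-4 mutant and 34 in the interaction, including every gene reported there. The 1 CPM filter gave 3 for the interaction. The DESeq2 test called 234 genes in lamin Y59C and 11 in the cec-4 mutant against wild-type, 240 and 250 in the double mutant against lamin Y59C and the cec-4 mutant, and 75 in the interaction. With the compared groups alone, 124 genes were called in lamin Y59C against wild-type and 156 in the double mutant against lamin Y59C. An adjusted p under 0.01, which is stricter by construction, left 12, 61, 9, 17 and 2 genes, and a fold of at least 2 left 30, 61, 28 and 30, both without the cec-4 mutant against wild-type and the fold also without the interaction. With the letters as a replicate block, the counts were 27, 3, 146, 28, 58 and 4, the share nearer wild-type was 62.96%, and 6 genes were called back. Of the named calls, 109 of 176 held under the block and 67 were lost. The call of srw-85 in the double mutant against the cec-4 mutant ended too (adjusted p = 0.0733). Camera then called 8, 7, 13, 4, 14 and 8 lists, against 8, 7, 13, 5, 15 and 8. Deviations of same-letter libraries correlated at -0.221 to 0.195 between groups, so the letters do not pair the libraries across all groups. The correlation was 0.195 between lamin Y59C and the double mutant. It was -0.221 between the cec-4 mutant and lamin Y59C, and -0.192 between the cec-4 mutant and the double mutant. A batch shared by only some groups was not tested. With each library left out, the counts ranged over 8 to 178, 3 to 9, 37 to 440, 6 to 166, 11 to 140 and 1 to 35. Leaving out a double mutant library ended the most named calls (67 and 61 of 176 held), and the lone library left was assumed to vary like the other groups. The share of genes nearer wild-type, reported as 69.9%, ranged from 37.5% to 78.9%. It was lowest without wild-type b (42.3%) and without lamin Y59C a (37.5%, of few genes), and was 50.0% (6 of 12 genes) at an adjusted p under 0.01. The slopes in those fits with a library left out were 0.801 and 0.366, on either side of the reported 0.547. The odds ratio of called genes on arms in the double mutant against wild-type, 0.749, did not pass with wider arms (0.810) or at an adjusted p under 0.01 (0.531). It did not pass without wild-type a, wild-type b or double mutant a either, over a range of 0.453 to 0.805. Except where stated, the cause was not tested. Fold changes of genes with few counts rest on few reads, as in col-41, where lamin Y59C had 1 and 5 counts.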

Other observations

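In this part, the tests of library depth and of the moulting cycle for the collagens were chosen only after the result was seen.

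Ribosomal protein genes showed small median shifts. In the double mutant against lamin Y59C their median was 0.10 (camera adjusted p = 1.82e-07; adjusted p = 0.902 with an estimated correlation), and against the cec-4 mutant it was 0.11 (adjusted p = 4.21e-08; adjusted p = 0.674 with an estimated correlation). Of 78 genes, edgeR called 0 in both, 5 and 3 had an unadjusted p under 0.05, and DESeq2 and the counts adjusted over the list alone gave 0. The estimated correlation between these genes was 0.807 and 0.804, far above the preset value of 0.01. Their summed CPM was 168641 and 145773 in the cec-4 mutant and 165033 and 175674 in the double mutant, so these libraries overlapped. It was 152899 and 160945 in lamin Y59C and 160413 and 165353 in wild-type, and the median of lamin Y59C against wild-type was -0.05. Of 46 genes of glycolysis and the citric acid cycle, 0 were called in lamin Y59C against wild-type, with a median of -0.09 (camera adjusted p = 3.41e-05; adjusted p = 0.849 with an estimated correlation); 8 had an unadjusted p under 0.05, DESeq2 called 1 lower, and 0 passed adjusted over the list alone. Transcripts of 72 sperm genes summed to 79.3 to 84.4 CPM in a library, those of 25 early embryo genes to 353 to 378 CPM, and 6 vitellogenin genes to 22 to 32 counts.

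The gene R03G8.1 (X:13084573-13087646, WBcel235), chosen after its values were seen, had 0 counts in all 4 libraries without the transgene and 48 to 184 counts in each of the 4 libraries with it. This was at least 162-fold higher, with a floor of 3 counts over the group. Of all genes it was the 1 with at least 20 counts in each library of one side and 0 in all of the other; the reverse split and the 2 splits by cec-4 gave 0. No explanation was tested for it.

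Transcripts of srw-85 were high in both strains without CEC-4. A larger copy number or opened region over most of the surrounding 100 kb on each side was argued against by its neighbours. The 32 other tested genes within 100 kb had a median log2 change of 0.112 in the cec-4 mutant (-0.02 to 0.28), and 0 were called by edgeR. A change limited to srw-85 or to a few adjacent genes would not move that median. Such a smaller change therefore stays open. Reads moved from other srw genes were argued against as well, since the other 106 srw genes together had 19.3 CPM in wild-type and 20.7 CPM in the cec-4 mutant, less than the gain of 53.0 CPM. A general rise of genes on autosome arms was not seen, as the median change of arm genes minus that of centre genes was -0.00462 (-0.00921 to 0.000830). That interval came from 1000 resamples of genes, which are not independent, and it holds no variation between libraries. A direct effect of losing CEC-4 at this gene and a variant carried along with the cec-4 allele stay open; both cec-4 strains may share such a variant, and this was not tested.

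Of the collagens, 9 were called lower in lamin Y59C, and were chosen here for that. They summed to 30.0 and 25.5 CPM in wild-type, 19.4 and 27.2 CPM in the cec-4 mutant, 5.70 and 9.31 CPM in lamin Y59C, and 15.5 and 15.4 CPM in the double mutant. Without col-77, the other 8 summed to 15.0 and 14.7 CPM in wild-type, 14.5 and 21.1 CPM in the cec-4 mutant, 1.07 and 2.97 CPM in lamin Y59C, and 12.4 and 11.3 CPM in the double mutant. Against wild-type, col-77 had a lower value in the double mutant (-1.83) than in lamin Y59C (-1.22), but the tested difference of -0.61 ± 0.24 did not pass (adjusted p = 0.303). All 175 collagens summed to 3425 and 3160 CPM in wild-type, 3291 and 2956 CPM in the cec-4 mutant, 3803 and 3404 CPM in lamin Y59C, and 2811 and 2955 CPM in the double mutant, so collagens summed together did not fall in lamin Y59C. Library depth was argued against, because the mean total of lamin Y59C was 0.9748 of that of the shallower wild-type library, which had 52 counts of col-41 against 1 and 5 in lamin Y59C. All 9 were still called with the deeper wild-type library thinned. A candidate explanation is that lamin Y59C cultures were at another point of the moulting cycle, in which collagens are made in waves. Of 91 collagens that were not called, 27.5% had an unadjusted p under 0.05 (18.6% to 37.8%), 10 of these 25 higher, against 14.6% of all tested genes; of 46 moulting genes it was 17.4% (7.82% to 31.4%), an interval that includes 14.6%. Those 8 moulting genes were all lower, and camera placed the list lower (median -0.02, adjusted p = 0.0462; adjusted p = 0.849 with an estimated correlation). EdgeR called 0 of the list, DESeq2 called 1 lower and 0 passed adjusted over the list alone. Camera placed 48 pharyngeal cuticle genes lower as well (adjusted p = 0.0382; adjusted p = 0.849 with an estimated correlation). Of these edgeR called 0, 12 had an unadjusted p under 0.05, DESeq2 called 2 lower and 1 was lower adjusted over the list alone. Whether these shifts belong to a moulting cycle was not tested further. Such a share was not particular to cuticle genes. Of 32 starvation and dauer genes, 12 had an unadjusted p under 0.05 in lamin Y59C against wild-type. EdgeR called 1 of that list, and DESeq2 called 2 higher and 1 lower. The labels do not say whether the libraries of a genotype came from separate cultures, so a shift in timing by the genotype and one by the culture were not separated.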
